A study of Rattus norvegicus with 24 samples.

How the data were processed

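The FPKM values of the mRNA table and the values of the miRNA table were computed by the authors and used as deposited. The miRNA table is named as FPKM too. Its values were taken here as RPM, reads scaled to the library total, because each column sums to 1000000. Per the submitters' processing notes, HISAT2, DESeq2 and the genome build Rnor_6.0 were used, with roles and versions not given in the sources used here. Per the labels, total RNA was taken with TRIzol from the proliferative zone, rRNA was depleted for the mRNA libraries, and small RNA libraries were made for miRNA. The deposited RPM columns each sum to the same total, and the reads behind them were recovered here from the smallest step of the values, with 100% of recovered values within 0.05 of a whole read. The deposited FPKM values have no such common step, so no mRNA reads were recovered. The program and the denominator behind the FPKM values are not given in the sources used here.

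Everything else was computed here. Values were set to log2(value + 1), features with a value of at least 1 in at least 3 of the 12 libraries were tested, and the 4 groups of each assay were fitted together in limma 3.58.1 (R 4.3.3) with a mean-variance trend and robust variances, 8 residual degrees of freedom and Benjamini-Hochberg adjustment at a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The gene lists, the comparisons, the filter and most alternatives were fixed before the data were examined, and those added afterwards are TPM scaling, the scaled fits without single libraries, and edgeR and DESeq2 on recovered reads. Recovered miRNA reads were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Changes relative to the median gene come from a fit after median-of-ratios scaling of the deposited values. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

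Genes were named by a fixed rule. In the swaddling comparisons of each day and between the ages of controls these are the 12 higher and 12 lower genes with the largest fold change among those past the threshold, with a mean of at least 5 FPKM in the higher group, groups that do not overlap and a gene symbol. Averaged over both days and in the remaining mRNA comparisons 5 and 5 were named, and for miRNAs 8 and 8 with a mean of at least 10. Where fewer than 5 features passed, the 12 genes or 8 miRNAs with the smallest p were named and said not to pass. For a list described, up to 4 passing members with the largest fold change were named, and a fixed set of chondrocyte genes and miRNAs was looked at in every comparison. Pthlh of that set was not among the tested genes. Gene identity is the symbol and Ensembl ID of the mRNA table, which gives no positions. Symbols were checked against a table of the assembly GRCr8, used only for names, where 18268 of 21935 symbols matched. A check against the gene spans of that table was run and left out, because those spans do not belong to the authors' build. In it, genes with shorter spans tended to rise more at day 5, while oxidative phosphorylation genes still lay above lists matched for span and level. A gene span is not a transcript length, so neither observation decides the question. A bias of FPKM with transcript length was therefore not excluded. The mRNA and miRNA libraries were paired by group and replicate number.

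The pipeline was tested on simulated data with 3 libraries per group. With changes of log2 1 and log2 2 in 100 genes each, limma recovered 44 and 87 and called 7 unchanged genes of 12827. With 30 miRNAs each, limma recovered 0 and 4, edgeR 0 and 4, and DESeq2 2 and 14 with 3 unchanged called. A list raised as a whole was recovered at a preset and at an estimated correlation, with 0 other lists called. The simulated features varied independently of each other, and no library was shifted as a whole. The real mRNA lists had a median estimated correlation of 0.39 between members. The simulation therefore does not show how often limma or camera makes false calls in the real data.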

Results

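Tight swaddling of newborn rats is used as a model of developmental dysplasia of the hip, in which the socket of the hip joint forms poorly. The study profiled mRNA and miRNA in the proliferative zone of the acetabular cartilage, the layer of the socket in which chondrocytes divide, to ask how swaddling alters expression there. The labels describe 6 swaddled and 6 control neonates of the same litter, sampled 5 or 10 days after birth. Each of the 4 groups held 3 mRNA libraries and 3 miRNA libraries, 24 in all. With 3 animals against 3, a two-sided exact test of a single gene cannot give a p below 0.1, so differences were tested with limma across all features. The mRNA table listed 22050 genes as FPKM, a value scaled to transcript length and library size, of which 12827 were tested. Its columns summed to between 220633 in control day 10 replicate 3 and 467177 in swaddled day 10 replicate 3, and the number of mRNA reads is unknown. The miRNA table listed 647 annotated and 1031 predicted miRNAs, of which 449 and 140 were tested. Its values were taken as RPM, reads scaled to the library total. Its recovered depth ran from 6123205 reads in swaddled day 10 replicate 1 to 12975993 reads in swaddled day 10 replicate 2. Fold changes below are on the log2(value + 1) scale, and the adjusted p-values of single genes are limma's after Benjamini-Hochberg adjustment.

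The libraries were first compared with each other. No 2 libraries held identical values. In mRNA the first 2 principal components carried 51.5% and 17.6% of the variance, and in miRNA 52.1% and 15.3%. The 3 swaddled day 10 libraries lay apart. Replicate 2 was closest to control day 10 replicate 2 (r = 0.956 across genes), replicate 3 to swaddled day 5 replicate 3 (r = 0.954) and replicate 1 to swaddled day 5 replicate 1 (r = 0.947). Genes are not independent replicates, so these r describe similarity only. Globin genes took 6.78%, 6.998% and 8.39% of the FPKM total in day 5 controls and 16.2%, 11.3% and 12.8% in swaddled day 5 libraries. In day 10 controls they took 1.15%, 0.545% and 1.59%, and in swaddled day 10 libraries 3.89%, 0.481% and 19.7%. Mitochondrial genes took 30.5%, 17.0% and 27.9% in day 5 controls against 9.57%, 15.5% and 7.74% in swaddled day 5 libraries. At day 10 their share was 15.5%, 12.6% and 14.0% in controls and 31.9%, 10.5% and 8.26% in swaddled animals.

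**Figure D1:**
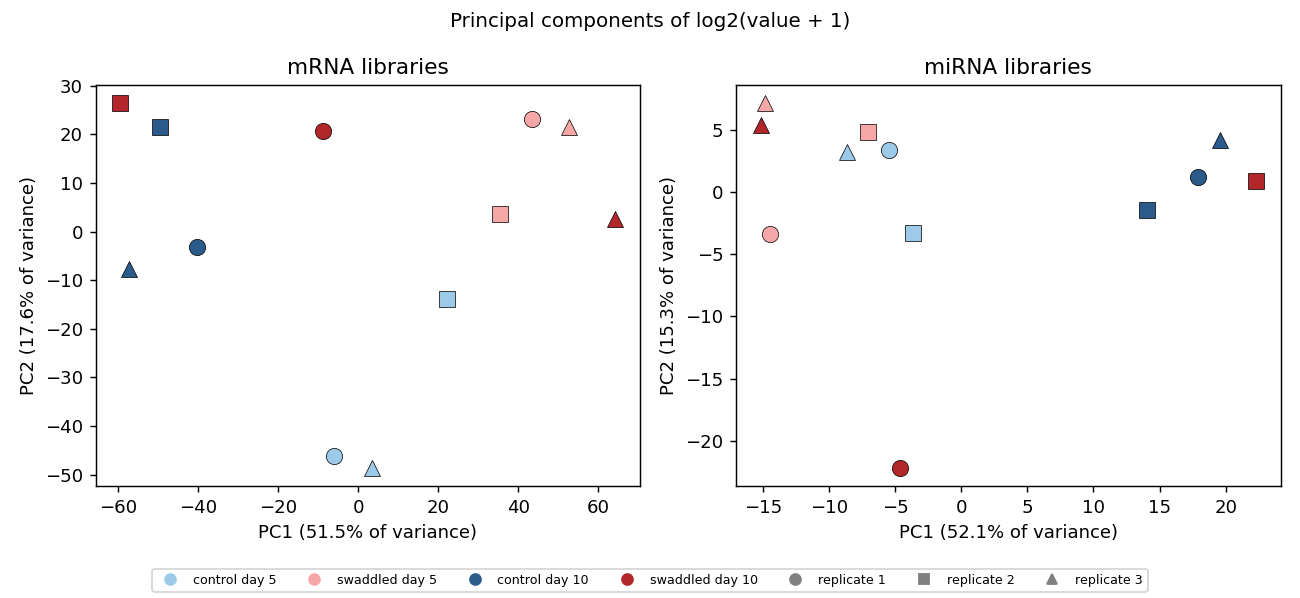
Principal component scores (PC1 on the horizontal axis, PC2 on the vertical axis, arbitrary units) of the mRNA and miRNA libraries on the log2(value + 1) scale, with blue controls, red swaddled animals, and circles, squares and triangles for replicates 1, 2 and 3. The mRNA library of swaddled day 10 replicate 3 sits at a PC1 of 64.4, beyond the swaddled day 5 libraries at 35.5 to 52.7, and swaddled day 10 replicate 2 sits at -59.5, beside the day 10 controls at -57.3 to -40.4.

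Swaddled and control animals were compared at day 5 to find what 5 days of swaddling had changed. Ncmap, a membrane protein of myelinating Schwann cells (ENSRNOG00000048139), rose from 2.05 ± 0.38 FPKM to 14.5 ± 3.96 FPKM (SD, n = 3), by 2.32 ± 0.25 (SE; adjusted p = 0.00423). Romo1, a small mitochondrial inner membrane protein that modulates reactive oxygen species (ENSRNOG00000045555), was listed at 1.44, 2.59 and 0 FPKM in controls and at 15.9, 9.96 and 20.7 FPKM in swaddled animals (adjusted p = 0.00537). Sec61g, a subunit of the channel that takes secreted proteins into the endoplasmic reticulum (ENSRNOG00000005203), rose by 2.47 ± 0.35, from 16.6 ± 6.74 FPKM to 95.4 ± 29.9 FPKM (adjusted p = 0.00537). Dlk1, an imprinted inhibitor of differentiation (ENSRNOG00000019584), rose by 2.42 ± 0.56, from 59.6 ± 24.9 FPKM to 304.6 ± 62.1 FPKM (adjusted p = 0.0200). Also among the 12 rises named by rule were Dpm3 (2.17), Ndufa3 (1.99), H2afz (1.96), Rpp21 (1.91), Prx (1.88) and Snrpd2 (1.87). Rps2 (2.37) and Hist1h2ail1 (1.97) belong to families with near-identical copies and are uncertain. The falls that met the rule were Nupr1l1 (-1.55, adjusted p = 0.0252), the ETS factor Elk4 (-1.09, adjusted p = 0.0283) and the nonsense-mediated decay factor Upf3a (-0.81, adjusted p = 0.0452).

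In all, limma called 2010 genes at day 5, of which 2004 were higher and 6 lower in swaddled animals, 99.7% higher. The median of all tested genes was itself higher by 0.44, and the size factors of the libraries moved the same way, from 0.787, 1.06 and 0.771 in controls to 1.22, 1.20 and 1.34 in swaddled animals. Relative to that shift, by median-of-ratios scaling, 42 genes passed, 29 higher and 13 lower (69.0% higher), and 32 genes passed under both. Ncmap (1.88, adjusted p = 0.0142), Romo1 (adjusted p = 0.0441), Sec61g (1.95, adjusted p = 0.0418), Dpm3 (1.67), H2afz (1.44) and Snrpd2 (1.36) still rose relative to the median gene, and Elk4 (-1.59) and Upf3a (-1.29) still fell. Dlk1 stood 1.89 above the median gene without passing (adjusted p = 0.159), and Nupr1l1 stood at -2.06 (adjusted p = 0.0556). The count with deposited values was 40 without swaddled replicate 3, 53 without control replicate 1, 296 without control replicate 3, 427 without swaddled replicate 1 and 1158 without swaddled replicate 2. It was 3272 without control replicate 2 and 3920 without swaddled day 10 replicate 3, and with the scaling it was 106, 2 and 1 without swaddled day 10 replicate 3, day 10 replicate 1 and day 5 replicate 1.

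The chondrocyte genes fixed beforehand did not pass at day 5. Col2a1, the main collagen of cartilage, stood at 782 ± 18.9 FPKM in controls and at 1005, 5262 and 4092 FPKM in swaddled animals (1.83 ± 0.95, adjusted p = 0.184). Acan, which encodes aggrecan, differed by 1.41 ± 0.54 (adjusted p = 0.0883), Sox9, the chondrocyte master regulator, by 0.60 (adjusted p = 0.356), and the hypertrophy genes Col10a1 and Ihh by 1.42 and 1.15 (adjusted p = 0.515 and 0.435). Prg4, the lubricin of the joint surface, differed by -0.87 (adjusted p = 0.480). The proliferation marker Mki67 differed by 0.24 and the joint gene Gdf5 by 0.23 (adjusted p = 0.773 and 0.595), and both turned negative relative to the median gene, at -0.29 and -0.04.

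**Figure D2:**
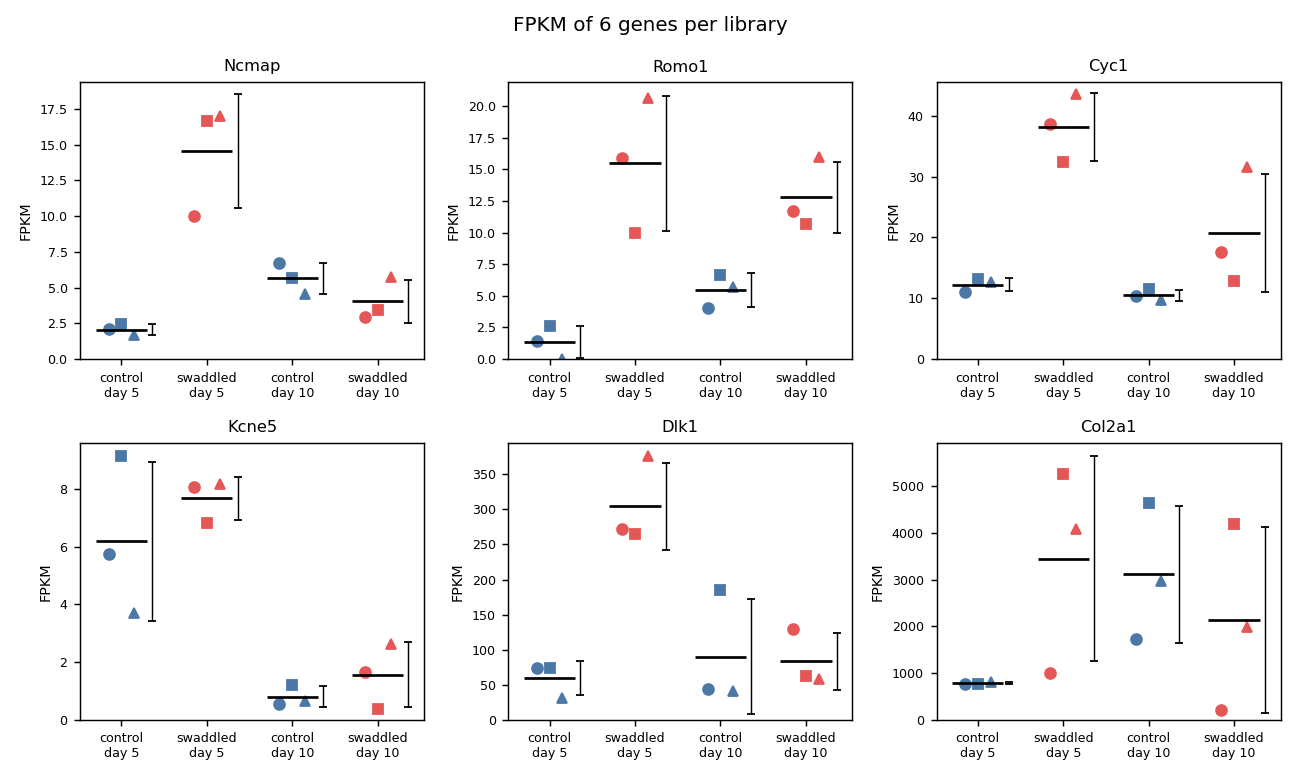
FPKM of Ncmap, Romo1, Cyc1, Kcne5, Dlk1 and Col2a1 (vertical axes) in the 4 groups (horizontal axes), where each point is a library, blue for controls and red for swaddled animals, with circles, squares and triangles for replicates 1, 2 and 3, a black line for the mean and an error bar for the SD (n = 3). Ncmap lies between 1.66 and 2.42 FPKM in day 5 controls and between 9.98 and 17.0 FPKM in swaddled day 5 animals.

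Gene lists fixed beforehand were tested against all other genes with camera at a preset correlation of 0.01, and 19 of 37 lists passed at day 5, 5 higher and 14 lower. Genes of oxidative phosphorylation ranked higher (adjusted p = 3.53e-06, and 0.679 with an estimated correlation), with 26 of 45 members past the threshold over all genes and 30 adjusted over the list alone, a mean of 0.87 and a mean of 0.35 relative to the median gene. Cyc1 of complex III rose by 1.56, Uqcrfs1 by 1.55, Sdhc of complex II by 1.53 and Ndufa2 of complex I by 1.51, while the mitochondrial share of FPKM was lower in these libraries. Genes of cholesterol synthesis ranked higher too (adjusted p = 3.53e-06, and 0.679 with an estimated correlation), with 12 of 20 members past the threshold and 15 adjusted over the list alone. Fdps (1.32), Fdft1 (1.22) and the regulator Srebf2 (1.14) rose. Ribosomal protein genes (26 of 71 higher, 42 adjusted over the list alone) ranked higher at an adjusted p of 7.4e-05 (0.808 with an estimated correlation), with copies that make single members uncertain. Schwann cell markers ranked higher (adjusted p = 0.0455, and 0.679 with an estimated correlation), with 3 of 10 members past the threshold, Ncmap, Prx and Pmp22 (1.40), and 8 adjusted over the list alone. Its members did not always move together. From day 5 to day 10 controls the mean of Ncmap went from 2.05 to 5.64 FPKM, and that of the myelin gene Mbp from 5.32 to 0.80 FPKM. Ncmap alone therefore does not stand for the list. Autophagy genes ranked higher (adjusted p = 0.0365, and 0.808 with an estimated correlation), with 10 of 27 members past the threshold, 14 adjusted over the list alone, led by Atg4b (1.15) and Map1lc3a. None of the 19 calls held with an estimated correlation, where the smallest adjusted p was 0.679. FPKM depend on transcript length, and a length bias was not excluded for these lists or for genes of small proteins such as Romo1, Sec61g, Ndufa3 and Snrpd2.

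Being called lower at day 5 did not mean falling, as most of these 14 lists moved upward by less than the median gene. Only the markers of osteoblasts (mean -0.12, adjusted p = 3.89e-06) and B cells (mean -0.08, adjusted p = 6.14e-05) had a negative median and mean, both at an adjusted p of 0.679 with an estimated correlation. The joint surface list was called lower (adjusted p = 2.06e-05, and 0.679 with an estimated correlation) with a median of 0.03 and a mean of -0.00, and the other 11, such as fibroblasts (mean 0.11, adjusted p = 0.000272, and 0.679 with an estimated correlation), had a positive median and mean. Skeletal muscle markers had a mean of 0.64, above the shift of the median gene, and were still called lower (adjusted p = 0.000689, and 0.71 with an estimated correlation). With the scaling 4 lists passed, all higher: oxidative phosphorylation (adjusted p = 2.38e-09), ribosomal proteins (2.38e-09), cholesterol synthesis (1.32e-05) and Schwann cells (0.00115), and none passed with an estimated correlation. The cartilage matrix list did not pass (adjusted p = 0.824), although 25 of its 27 members were positive with a mean of 1.22. Its mean per library was 5.11, 7.10 and 7.0 in swaddled animals against 5.15, 5.63 and 4.78 in controls. Erythroid markers were positive in 16 of 16 genes (mean 1.27, adjusted p = 0.172), beside the higher globin share of these libraries. Of the cell cycle genes 6 of 43 passed, no larger a share than the 2010 of all 12827 tested genes, and 5 adjusted over the list alone. Among the 6 were Ccnb1 (1.23), Mcm5 (1.19), Cdk2 (1.04) and Cdk1 (1.03), and the list did not pass (adjusted p = 0.814).

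At day 10 the same comparison asked what 10 days of swaddling had changed, and no gene passed limma's threshold. At an unadjusted p under 0.05 there were 1651 genes, 1461 higher and 190 lower, and the smallest adjusted p was 0.25. The gene with the smallest p, Tm2d3 (ENSRNOG00000011290), was listed at 0 in all 3 controls and at 1.18, 1.42 and 1.72 FPKM in swaddled animals. The next were Mad2l2 (from 3.88 ± 0.864 FPKM to 8.64 ± 0.424 FPKM, adjusted p = 0.359) and Ndufa2 (1.11 ± 0.20, adjusted p = 0.359), followed by the respiratory chain genes Cox5a (1.54), Uqcc2 (0.91) and Cox14 (1.19). Ssna1 (0.89), Vamp8 (1.02), Snrpb (0.97), Rangap1 (1.02), Hist1h2bl (2.31) and Ap2s1 (1.07) completed the 12. Col2a1 stood at 1727, 4641 and 2972 FPKM in controls and at 213.7, 4187 and 1990 FPKM in swaddled animals (-1.25 ± 0.95, adjusted p = 0.548). Acan differed by -0.51, Sox9 by -0.77, Prg4 by -1.34 and Mki67 by 1.06 (adjusted p = 0.667, 0.459, 0.489 and 0.420). The median gene was higher by 0.20, no gene passed with the scaling either, and without swaddled replicate 2 the count was 477.

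Of the lists, 24 of 37 passed camera at day 10, 8 higher and 16 lower, and 24 passed with the scaling. Cartilage matrix genes ranked lower (adjusted p = 1.64e-09, and adjusted p = 0.323 with an estimated correlation), with 1 of 27 members positive, a mean of -0.67 and no member past the threshold. Its mean per library was 4.34, 6.20 and 5.78 in swaddled replicates 1 to 3 and 5.87, 6.45 and 6.02 in controls, so replicate 1 lay lowest. Hedgehog and PTHrP signalling (mean -0.42, adjusted p = 1.64e-09), the circadian clock (mean -0.31, 6.82e-08), the joint surface (mean -0.46, 6.19e-06) and chondrocyte transcription factors (mean -0.26, 1.68e-05) ranked lower as well. For these 4 lists the adjusted p was 0.275 with an estimated correlation. Cell cycle genes ranked higher (mean 0.79, 42 of 43 positive, adjusted p = 1.33e-08, and adjusted p = 0.528 with an estimated correlation). Oxidative phosphorylation (mean 0.57, adjusted p = 6.6e-08, and 0.528 with an estimated correlation) had 0 members past the threshold over all genes and 10 adjusted over the list alone. Erythroid (mean 2.53, adjusted p = 5.03e-05) and neutrophil markers (mean 2.49, adjusted p = 0.000672) ranked higher, at adjusted p = 0.528 and 0.547 with an estimated correlation. Per library the erythroid mean was 5.85, 1.94 and 8.14 in swaddled animals and 3.66, 2.14 and 2.55 in controls, and the cell cycle mean was 3.83, 3.56 and 5.14 against 3.47, 3.48 and 3.20. Hypertrophy genes were called lower with a mean of 0.00 and a median of 0.02, and matrix proteases with a mean of 0.03 and a median of -0.05. None of the 24 held with an estimated correlation.

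**Figure D3:**
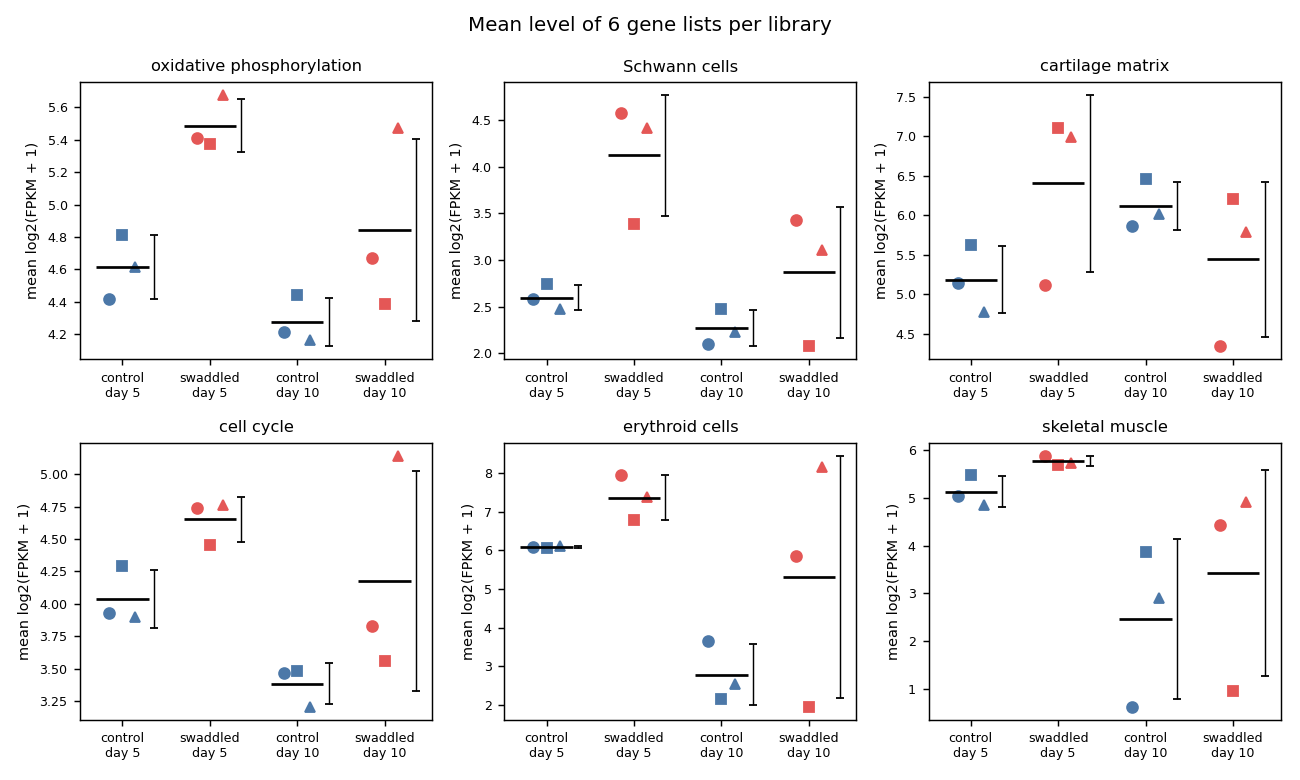
Mean log2(FPKM + 1) of the members of 6 gene lists (vertical axes) in the 4 groups (horizontal axes), where each point is a library, blue for controls and red for swaddled animals, with circles, squares and triangles for replicates 1, 2 and 3, a black line for the mean and an error bar for the SD (n = 3). The erythroid list reads 5.85, 1.94 and 8.14 in the 3 swaddled day 10 libraries and 3.66, 2.14 and 2.55 in the day 10 controls.

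Averaged over both days, swaddled animals were higher in Mbp, a myelin protein (2.35 ± 0.66, adjusted p = 0.0365), in Romo1 (adjusted p = 0.00527) and in the multi-copy genes Hbb (2.44, adjusted p = 0.0417) and Hist1h2ail1 (2.02), which are uncertain. Stfa3 also passed (adjusted p = 0.0292) and was listed at 0 in all day 10 controls. Lower were Cd248, a marker of fibroblasts and pericytes (-1.27 ± 0.32, adjusted p = 0.0237), Nupr1l1 (-1.06, adjusted p = 0.0252), Abi3bp (-0.77), the ETS factor Etv1 (-0.62) and Filip1l (-0.59). limma called 2460 genes, 2451 higher and 9 lower, beside a median shift of 0.32, and 99 with the scaling, 75 higher and 24 lower, of which 80 passed under both. Col2a1 (0.29), Acan (0.45), Sox9 (-0.09), Mki67 (0.65), Col10a1 (0.50), Ihh (0.44), Gdf5 (0.01) and Prg4 (-1.10) did not pass, with adjusted p from 0.199 to 0.973. Relative to the median gene Romo1, Hist1h2ail1, Nupr1l1 (-1.44), Etv1 (-0.96) and Filip1l (-0.97) passed, and Hbb, Mbp, Stfa3, Cd248 and Abi3bp did not. The scaled count of 99 was 1 without swaddled day 10 replicate 1, 1 without swaddled day 5 replicate 1 and 313 without swaddled day 10 replicate 3, and TPM scaling gave 0. Leaving out swaddled day 5 replicate 3 gave 575 calls, control day 5 replicates 1 and 3 gave 615 and 889, swaddled day 5 replicate 1 gave 966, and control day 10 replicates 1 and 3 gave 1008 and 1019. Without swaddled day 10 replicate 2 there were 4395 calls. Of 37 lists 20 passed, 5 higher and 15 lower, and none of the 20 held with an estimated correlation (smallest adjusted p = 0.249). Cell cycle genes were among those higher (mean 0.70, adjusted p = 0.000376, and adjusted p = 0.75 with an estimated correlation), with 18 of 43 members past the threshold and 28 adjusted over the list alone.

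Whether the effect of swaddling differed between the days was tested as an interaction, day 10 minus day 5. Ncmap had the smallest p: its difference was 2.32 at day 5, and at day 10 it read 5.64 ± 1.09 FPKM in controls against 4.03 ± 1.49 FPKM in swaddled animals, an interaction of -2.75 ± 0.36 (adjusted p = 0.0673). Relative to the median gene it was the 1 gene to pass (-2.52, adjusted p = 0.0244), and with the scaling 0 genes passed without swaddled day 10 replicate 1. The 11 genes that followed, among them the transporter Slc22a17 (-1.58), Rabac1 (-1.59), the fatty acid oxidation enzyme Acads (-1.26), and Fgfrl1 (-1.66), all had an adjusted p of 0.407. Acan (-1.91), Col2a1 (-3.08) and Sox9 (-1.37) lay in the same direction (adjusted p = 0.483, 0.508 and 0.542). limma called 0 genes, with 1212 at an unadjusted p under 0.05, and 1 gene without swaddled day 5 replicate 1 or without swaddled day 10 replicate 3. Cartilage matrix genes ranked lower in the interaction (mean -1.89, 1 of 27 positive, adjusted p = 2.81e-05, and 0.669 with an estimated correlation), as did cholesterol synthesis (mean -0.65, adjusted p = 3.53e-06, 6 of 20 lower adjusted over the list alone and 0 over all genes). Neutrophil markers (mean 2.10, adjusted p = 3.05e-09) and erythroid markers (mean 1.25, adjusted p = 9.2e-07) ranked higher. These were 4 of 15 lists past the threshold, and every 1 of the 15 had an adjusted p of 0.669 with an estimated correlation. Across the 12827 genes the effects at the 2 days were correlated (r = 0.361, rho = 0.373), and 3 of 100 splits of the animals within days, drawn at random with the real one included, gave a correlation as large in size. Across the 589 miRNAs r was 0.113 and rho 0.117, and 46 and 57 of 100 splits gave one as large. Genes are not independent replicates. These correlations and splits used deposited values, in which the median gene was higher by 0.44 at day 5 and 0.20 at day 10. The splits were not run after scaling, so they cannot part a shared response of genes from a shift of whole libraries.

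Development between day 5 and day 10 was compared within controls. Kcne5, a regulatory subunit of potassium channels, fell from 6.19 ± 2.76 FPKM to 0.80 ± 0.36 FPKM (SD, n = 3; -1.95 ± 0.35, adjusted p = 0.0457). Hypk (-1.83), Nsrp1 (-1.53), Srp14 of the signal recognition particle (-1.42), Upf3a (-1.36) and Pdap1 (-1.31) fell as well. Rises that met the rule included those of the guanine nucleotide exchange factor Ngef (1.84 ± 0.28, from 3.69 ± 0.792 FPKM to 15.9 ± 3.94 FPKM, adjusted p = 0.0342) and the endosomal Rab4b (1.75, adjusted p = 0.0342). Obsl1 (1.52), Fam193b (1.41), Scarf2 (1.37), Slc22a17 (1.36), Dtx3 (1.34), Kcnk6 (1.34), Arhgef19 (1.32), Rhoc (1.29) and Rpp21 (1.27) rose as well. Acan, Col2a1 and Sox9 stood 1.40, 1.88 and 0.97 higher at day 10 without passing (adjusted p = 0.164, 0.262 and 0.238), and Mki67 stood at -1.69 (adjusted p = 0.128). limma called 79 genes, 71 higher and 8 lower (89.9% higher), with a median shift of 0.05. With the scaling it called 189, 62 higher and 127 lower (32.8% higher), and 43 genes passed under both. The count fell to 0 without any 1 of the control libraries of either day, swaddled day 5 replicates 1 or 2, or swaddled day 10 replicate 1. It was 1 without swaddled day 5 replicate 3, 955 without swaddled day 10 replicate 2 and 1811 without swaddled day 10 replicate 3. Leaving out a swaddled library cannot move these fold changes, only the variance estimated over the 4 groups.

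Among the lists, 17 of 37 passed between the ages of controls, 7 higher and 10 lower, and 16 with the scaling. Markers of skeletal muscle (mean -2.66, adjusted p = 5.69e-11), erythroid cells (mean -3.31, 2.13e-09), neutrophils (mean -3.61, 2.78e-08) and adipocytes (mean -1.97, 2.69e-07) ranked lower at day 10, beside a globin share that went from 7.39% ± 0.875 to 1.09% ± 0.523. Their adjusted p was 0.652 with an estimated correlation. No member of these 4 lists passed over all genes, and adjusted over the list alone 1 of 24, 15 of 16, 9 of 15 and 7 of 9 were lower. Cell cycle genes ranked lower (mean -0.66, 3 of 43 positive, adjusted p = 2.2e-08, and 0.652 with an estimated correlation). Glycolysis and hypoxia genes ranked higher (mean 0.86, adjusted p = 1.19e-05, 0 of 29 past the threshold over all genes and 4 adjusted over the list alone), as did the circadian clock (mean 0.56, adjusted p = 0.000252, 0 and 8 of 17), both at an adjusted p of 0.652 with an estimated correlation. Mechanosensing genes ranked higher (adjusted p = 0.000506, and 0.652 with an estimated correlation), and the mechanically gated channel Piezo1 rose by 1.01 (adjusted p = 0.0457), the 1 member of 24 past the threshold, with 6 adjusted over the list alone. Cartilage matrix genes ranked higher (mean 0.93, 25 of 27 positive, adjusted p = 0.00256, and 0.652 with an estimated correlation), with 0 members past the threshold over all genes and 2 adjusted over the list alone. None of the 17 calls held with an estimated correlation.

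Within swaddled animals no gene passed between day 5 and day 10. There were 1038 genes at an unadjusted p under 0.05, the smallest adjusted p was 0.173, and the median gene stood 0.20 lower at day 10. Ncmap had the smallest p (-1.63 ± 0.25), followed by Ppp1r1a (-1.47), Lrrc39, Wnk2 (-1.12), Mlf1 (-1.57), Kcne5 (-1.87), Cited1 (-1.36), Cidea (-1.43) and Lmcd1 (-1.21). Col10a1 stood at -2.71 and Col2a1 at -1.20 (adjusted p = 0.611 and 0.665). Ccl5, Mrap and Asb12 complete the 12 and were listed at 0 in at least 1 day 10 library, as was Lrrc39. Without swaddled day 10 replicate 3, the library closest to the day 5 animals, limma called 2324 genes, and with the scaling 1093. Of 37 lists 19 passed, 10 higher and 9 lower. Schwann cell markers ranked lower (mean -1.25, 0 of 10 positive, adjusted p = 7.54e-05, 3 adjusted over the list alone), as did oxidative phosphorylation (mean -0.64, 1.47e-11) and skeletal muscle (mean -2.34, 1.47e-07), all at an adjusted p of 0.653 with an estimated correlation. Whether ageing differed between the treatments is the same contrast as the interaction.

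In miRNA no single feature passed limma's threshold in any comparison. At day 5 there were 24 miRNAs at an unadjusted p under 0.05 (smallest adjusted p = 0.881), and on recovered reads edgeR and DESeq2 called 0, with 31 and 39. miR-873-5p, miR-433-5p, miR-433-3p, miR-665, miR-380-5p, miR-770-5p, miR-341 and miR-493-5p had the smallest p and lay 0.93 to 1.50 higher in swaddled animals. miR-433-3p read 136 ± 35.4 RPM in controls and 344 ± 118 in swaddled animals, and miR-493-5p read 762 ± 84.7 and 1504 ± 131. Of these 8, miR-433, miR-665, miR-380, miR-770, miR-341 and miR-493 lie in the imprinted Dlk1-Dio3 cluster. Its protein-coding gene Dlk1 is among the day 5 rises with deposited values, but did not pass relative to the median gene. The cluster's list ranked higher (adjusted p = 3.95e-11, and adjusted p = 0.673 with an estimated correlation), with 64 of 74 members positive, a mean of 0.58 and no member past the threshold, beside a median miRNA higher by 0.17. Muscle miRNAs (mean 0.53) and nerve and brain miRNAs (mean 0.49) lay higher by about as much without passing (adjusted p = 0.401 for both). The let-7 family (mean -0.16, adjusted p = 0.00345) and the miR-29 family (mean -0.43, adjusted p = 0.0111) ranked lower, both at adjusted p = 0.673 with an estimated correlation. They were the 3 of 16 lists past the threshold.

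At day 10, 42 miRNAs had an unadjusted p under 0.05 and the smallest adjusted p was 0.476. On recovered reads edgeR called 0 (87 unadjusted) and DESeq2 called 24, all higher in swaddled animals, and limma called 111 without swaddled replicate 2. The DESeq2 calls were led by the predicted novel_miR_151 and novel_miR_98, with the same fold change and p (5.34, adjusted p = 0.000603). Predicted miRNAs took 5.40%, 1.16% and 2.15% of RPM in swaddled replicates 1 to 3 and 1.15%, 2.12% and 1.15% in controls. By limma the 8 with the smallest p were the predicted miRNAs novel_miR_629, novel_miR_769, novel_miR_37, novel_miR_875 and novel_miR_866 with miR-106b-5p (1.07), miR-141-3p (1.33) and miR-30a-5p (0.86). miR-140-5p, a miRNA typical of chondrocytes, read 24518, 21947 and 31490 RPM in controls and 8272, 28103 and 6167 in swaddled animals (-1.19 ± 0.47, adjusted p = 0.476). miR-140-3p differed by -0.71 and miR-455-3p by -0.91 (adjusted p = 0.562 and 0.476). The Dlk1-Dio3 list now ranked lower (mean -0.16, 26 of 74 positive, adjusted p = 2.5e-09, and adjusted p = 0.575 with an estimated correlation), beside a median miRNA higher by 0.25. The chondrocyte miRNA list ranked lower (mean -0.18, adjusted p = 0.00568) and the miR-17-92 clusters higher (mean 0.87, adjusted p = 0.0177), at adjusted p = 0.453 and 0.659 with an estimated correlation. Muscle miRNAs ranked higher (mean 1.36, adjusted p = 0.0276, and 0.659 with an estimated correlation). In the interaction the Dlk1-Dio3 list ranked lower (mean -0.73, 6 of 74 positive, adjusted p = 8.1e-24, and adjusted p = 0.270 with an estimated correlation). No single miRNA passed there by limma, edgeR or DESeq2 (18, 60 and 66 unadjusted). miR-16-5p (1.54) and miR-127-3p (-1.39) had the smallest p, at an adjusted p of 0.862. Over both days limma and edgeR called 0 (53 and 69 unadjusted), DESeq2 called 5, and limma 71 without swaddled day 10 replicate 2.

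Between the ages of controls, limma and edgeR called 0 miRNAs (133 unadjusted by limma) and DESeq2 called 14, 2 higher and 12 lower. limma called 62 and 65 without swaddled day 10 replicates 2 and 3. The smallest p belonged to miR-30a-5p (-1.32), miR-10a-5p (-2.46), the endothelial miR-126a-3p (-1.85) and miR-126a-5p (-1.86), miR-205 (-2.89), miR-139-5p (-2.43), miR-378a-5p (-2.47) and miR-145-5p (-1.95), all lower at day 10 with an adjusted p of 0.157. miR-140-5p stood 1.61 higher (adjusted p = 0.157). Of these, DESeq2 called miR-10a-5p, miR-205, miR-139-5p, miR-378a-5p and miR-140-5p (2.20, adjusted p = 0.0359). The median miRNA stood 0.45 lower, and relative to it miR-30a-5p read -0.73 and miR-140-5p 2.20. Muscle miRNAs ranked lower (mean -2.44, 0 of 9 past limma's threshold over all miRNAs and 9 adjusted over the list alone, adjusted p = 0.000754, and adjusted p = 0.530 with an estimated correlation), and DESeq2 called miR-1b, miR-133a-5p and miR-1-3p of that list. The cluster of miR-143 and miR-145 ranked lower (mean -1.85, adjusted p = 0.00707, 0 of 4 and 4 of 4). The Dlk1-Dio3 list ranked higher (mean 0.02, adjusted p = 5.47e-09). Both had an adjusted p of 0.455 with an estimated correlation. In swaddled animals limma and edgeR called 0 between the ages (67 and 72 unadjusted) and DESeq2 6, and limma called 50 without swaddled day 10 replicate 3. There miR-154-3p (-1.63), miR-665 (-2.10), miR-370-3p (-1.98), miR-409a-5p (-1.43), miR-543-3p (-2.37), miR-127-3p (-1.28), miR-341 (-1.76) and miR-532-3p (-1.83) had the smallest p, at an adjusted p of 0.219.

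Host genes and the miRNAs processed from their transcripts were compared across the 12 animals in 25 pairs, by Pearson's r and Spearman's rho with permutation tests adjusted over the pairs. Mcm7, a subunit of the replicative helicase, and its intronic miR-25 had r = 0.910 (adjusted p = 0.00125) and rho = 0.944 (adjusted p = 0.00150). Smc4 and miR-15b had r = 0.871 (adjusted p = 0.00125) and rho = 0.881 (adjusted p = 0.00317). Without the 2 animals farthest from the median of the host these 2 pairs had r = 0.704 and 0.715. In cartilage genes, Col27a1 and miR-455 had r = 0.763 and rho = 0.720 (adjusted p = 0.0111 and 0.0259), and Wwp2 and miR-140 r = 0.723 and rho = 0.748 (adjusted p = 0.0177 and 0.0196), or r = 0.555 and 0.530 without those 2 animals. In all 11 pairs passed by r, all positive, and 10 by rho, while 8 passed by r without the 2 farthest animals. After the group means were subtracted no pair passed by either measure, with r = 0.897 for Mcm7 and miR-25 and 0.530 for Wwp2 and miR-140 (adjusted p = 0.205 and 0.183 by permutation within groups).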

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

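The test of scaling between libraries and the test of pairs of marker lists were chosen only after the result was seen.

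Cers1, a ceramide synthase, and Fry were singled out for a crossing. Every swaddled library lay above every control at day 5 and below every control at day 10. Both shared the adjusted p of the genes named for the smallest p in the interaction, and choosing by that p favours a crossing. How many of the 12827 tested genes cross in this way was not counted, so the crossing alone does not make them rare. Cers1 also lay near the filter value of 1 FPKM. The difference of effects was -1.23 ± 0.24 for Cers1 and -1.45 ± 0.29 for Fry (SE; adjusted p = 0.407 for both, limma), so the difference did not pass. Cers1 stood at 0.574 and 1.42 FPKM in day 5 controls and swaddled animals and at 1.37 and 0.555 FPKM at day 10, and Fry at 8.89, 15.4, 22.6 and 12.9 FPKM in the same order.

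Of the genes called at day 5, 2004 were higher and 6 lower in swaddled animals. After median-of-ratios scaling 32 of the 2010 stayed called in the same direction. The authors' scaling between libraries may lie behind most of the remainder, and so may a general rise of transcripts in swaddled animals, and these cannot be told apart without reads or spike-ins. In the same libraries the FPKM totals went from 310370 ± 22219 to 414033 ± 17187 (SD, n = 3), and the mean mitochondrial share from 25.1% to 10.9%. TPM scaling, which sets the totals equal, left 20 genes called. How much of the rise goes with these differences was not tested. Of the 10 splits of the 6 day 5 animals, 1, the real one, gave as many genes (2010, highest other 0), and 10 splits are too few for a share under 0.05.

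Swaddled day 10 replicate 3 lay nearer to the day 5 libraries than to its own group. Its mean mRNA r was 0.930 with control day 5, 0.945 with swaddled day 5 and 0.832 with its own group. Replicate 1 did so less strongly, at 0.916, 0.928 and 0.894. In miRNA these values were 0.972, 0.971 and 0.932 for replicate 3 and 0.950, 0.948 and 0.934 for replicate 1. A position was then taken over 5411 genes that do not follow blood, neutrophil or muscle markers within groups. It ran from 0 at the day 5 control mean to 1 at the day 10 control mean. Swaddled day 10 replicate 3 sat at 0.00488, against 0.638 and 1.14 for the other swaddled day 10 animals. A mislabelled sample may therefore be the cause, but no day 5 library lay near day 10 (0.0507 to 0.272), as an exchange within the series would need. Leaving out genes that follow markers of blood, marrow or muscle raised its position by 0.124. The same step raised control day 10 replicate 1 from 0.714 to 0.899 and lowered control day 10 replicate 3 from 0.944 to 0.808. A move of this size is therefore not particular to swaddled day 10 replicate 3. In that library globin took 19.7% of FPKM, with Hba-a1 at 51023.5 FPKM and S100a8 at 502 FPKM, so other tissue stays open. A delayed maturation of a swaddled animal also stays open and was not tested.

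At day 5, 2 of 13 marker lists of other cell types lay more than 2 SE above the median gene in swaddled animals, Schwann cells (1.07 ± 0.35, SE) and erythroid cells (0.75 ± 0.37), and 0 lay more than 2 SE below. The other 11 lay within 2 SE, such as fibroblasts at -0.41 ± 0.22 and osteoblasts at -0.62 ± 0.40, and the cartilage matrix list stood at 0.71 ± 0.64. A lower share of cartilage cells may raise the markers of every other type alike, and 20 of 78 pairs of the 13 marker lists lay more than 2 SE apart. Another split of the 6 animals gave 21, so this explanation cannot be told apart from the spread between animals. By sign, 4 of the 13 lists lay above the median gene and 9 below it. A lower share of cartilage cells would not give the signs of those 9 or of the cartilage matrix list, but each lay within 2 SE. A biological change of nerve or blood supply under swaddling stays open and was not tested.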

How the results depend on the processing

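TPM scaling, the fits after median-of-ratios scaling without single libraries, and edgeR and DESeq2 on recovered reads were chosen only after the result was seen.

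Median-of-ratios scaling gave 42 genes at day 5, 99 for the mean of both days, 1 for the difference of effects and 189 between the ages of controls, with 4 gene lists at day 5. Quantile normalization gave 33, 162 and 1 for the first 3. TPM scaling gave 20 at day 5, 0 for the mean, 1 for the difference and 1511 between the ages of controls. Mki67 at day 5 turned to -0.29, -0.37 and -0.17 under median-of-ratios, quantile and TPM scaling, and Gdf5 to -0.0382 and -0.16 under the first 2. For the mean of both days Col2a1 turned to -0.10, -0.12 and -0.16 and Gdf5 to -0.18, -0.28 and -0.31 under the 3 scalings, and Acan to -0.0765 under quantile and -0.00234 under TPM scaling. Ihh between the ages of controls turned to 0.0480 under TPM scaling. miR-140-3p at day 5 turned to -0.0189 under median-of-ratios scaling, and miR-455-3p between the ages of swaddled animals to 0.35 under it and 0.22 under quantile normalization.

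Median-of-ratios scaling without swaddled day 10 replicate 3 gave 106 genes at day 5, 1 at day 10, 313 for the mean, 1 for the difference, 2895 between the ages of controls and 1093 between the ages of swaddled animals. There Mki67 at day 5 read -0.29 and Gdf5 -0.0393, and for the mean Col10a1 read -0.55, Mki67 -0.0843, Ihh -0.21, Col2a1 -0.20 and Gdf5 -0.0508. Prg4 read 0.81 in the difference, and Sox9 0.0690 and Acan 0.00625 between the ages of swaddled animals. Without swaddled day 10 replicate 1 the scaled counts were 2 at day 5, 1 for the mean, 0 for the difference and 1 between the ages of controls, with Mki67 -0.29 and Gdf5 -0.0379 at day 5, Col10a1 0.66 and Ihh 0.15 at day 10, Gdf5 -0.14 for the mean and Col2a1 0.24 between the ages of swaddled animals. Without swaddled day 5 replicate 1 they were 1 at day 5, 1 for the mean, 1 for the difference, 1 between the ages of controls and 2 between those of swaddled animals, with Mki67 -0.39 and C1qa -0.0344 at day 5, Gdf5 -0.12 for the mean and Prg4 0.16 in the difference.

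A fit of only the groups compared gave 4161 genes at day 5 and 1542 genes and 83 miRNAs between the ages of controls. Array weights gave 8628 genes at day 5, 4067 at day 10, 8310 for the mean, 4723 for the difference, 4051 between the ages of controls and 7569 between those of swaddled animals, and 7 miRNAs at day 10 and 172 between the ages of controls. The weights did not converge. With them Col10a1 read -0.63, Ihh -0.19, Col2a1 -0.75 and Gdf5 -0.0716 for the mean, Ihh 0.21 between the ages of controls, Gdf5 -0.12 between those of swaddled animals, and miR-140-3p -0.20 at day 5 and -0.0767 between the ages of swaddled animals.

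A minimum log2 fold change of 1 gave 607 genes at day 5 and 252 for the mean, by its construction. A pseudocount of 0.1 gave 1 gene at day 10 and 159 between the ages of controls, and a pseudocount of 5 gave 19 there, with Ihh at 0.11. No filter gave 41 there, a fit without trend and robust variances 16, and a stricter filter gave 1 gene for the difference. With the replicate number as a block, 0 genes passed between the ages of controls, 1407 at day 5 and 1848 for the mean, and the numbers do not pair the animals, as the best match of deviations was the animal of the same number for 1 of 6 numbered pairs in each assay. At day 5, 1986 and 2054 genes passed with pseudocounts of 5 and 0.1, 1801 without a filter, 1795 with a stricter filter, and 2019 without trend and robust variances.

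With an estimated correlation 0 lists passed in any of the 6 list counts, at day 5, day 10 and between the ages of controls in mRNA and miRNA. fry called 11, 0 and 0 gene lists and 0, 0 and 0 miRNA lists there. DESeq2 called 24 miRNAs at day 10, 5 for the mean, 14 between the ages of controls and 6 between those of swaddled animals, where limma and edgeR called 0. miR-140-3p at day 5 read -0.16 with edgeR and -0.21 with DESeq2, and miR-455-3p between the ages of swaddled animals 0.54 and 0.58.

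Leaving out each library in turn gave 40 to 3920 genes at day 5, 0 to 477 at day 10, 575 to 4395 for the mean, 0 to 1 for the difference, 0 to 1811 between the ages of controls and 0 to 2324 between those of swaddled animals. For miRNAs it gave 0 to 111 at day 10, 0 to 71 for the mean, 0 to 65 between the ages of controls and 0 to 50 between those of swaddled animals. Col10a1 ran from -1.43 to 0.18 between the ages of controls, from -1.91 to 0.94 at day 10 and from -0.24 to 1.18 for the mean. Col2a1 ran from -2.09 to 0.0508 between the ages of swaddled animals, from -2.14 to 0.00447 at day 10 and from -0.15 to 0.92 for the mean. Gdf5 ran from -0.12 to 0.42 between the ages of swaddled animals, from -0.0131 to 0.39 at day 5 and from -0.13 to 0.11 for the mean. Ihh ran from -0.66 to 0.81 between the ages of controls and from -1.11 to 0.40 at day 10. Mki67 ran from -0.0212 to 1.52 in the difference, Prg4 from -0.28 to 1.61 between the ages of swaddled animals and from -1.50 to 0.39 in the difference, and Sox9 from -0.26 to 0.24 for the mean. miR-140-3p ran from -0.16 to 0.57 between the ages of swaddled animals and from -0.51 to 0.57 at day 5, and miR-455-3p from -0.45 to 0.56 and, in the difference, from -0.81 to 0.21. None of the values that turned passed the threshold, and the cause was not tested for them. Where the library left out lies outside the groups compared, fold changes stay the same and only the variance estimate can change. This holds for the 1811 genes and 65 miRNAs between the ages of controls, both without swaddled day 10 replicate 3. The same holds for the fit of only the groups compared. For the remaining counts the cause was not tested, apart from the fold change minimum. The depth of the mRNA libraries is unknown, so what depth limits could not be worked out from FPKM.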

Other observations

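Every count of other splits below was planned, and no test in this part was chosen only after its result was seen.

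The mean effect of swaddling over both days was tested against 100 splits within days. For the 2460 genes called, 1 split, the real one, gave as many and the highest other gave 374. So large a count was thus rare among these splits, which were drawn at random and run on deposited values. They were not run after median-of-ratios scaling, where 99 genes passed. They therefore cannot part changes of many single genes from a shift of whole libraries, in which the median gene rose by 0.32. For the difference between the days the real count was 0 and the highest other 374. For miRNAs the real count was 0 for the mean (highest other 2) and for the difference (highest other 0). A real count of 0 is met by each of the 100 splits by construction, so these splits say nothing about chance.

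For comparisons of 3 against 3 animals the 10 splits are too few for a share under 0.05. For genes at day 10 the real count was 0 and the highest other 87, between the ages of controls 79 and 1 (1 split as large), and between the ages of swaddled animals 0 and 85, where other splits that call genes point to a structure of the samples. For gene lists the real count and highest other were 19 and 20 at day 5 (2 splits as large), 24 and 28 at day 10 (4 splits) and 17 and 24 between the ages of controls (4 splits). For miRNAs they were 0 and 0 at day 5, 0 and 11 at day 10 and 0 and 0 between the ages of either group (10 splits each), and for miRNA lists 3 and 6 (4 splits), 6 and 10 (4 splits) and, between the ages of controls, 6 and 10 (2 splits).

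miR-206-3p, a miRNA of skeletal muscle, read 33195, 613.3 and 7962 RPM in the swaddled day 10 animals and 625.7, 6094 and 1845 RPM in the day 10 controls. miR-144-3p, a miRNA of erythroid cells, read 214.8, 10.4 and 1251 RPM and 96.9, 4.87 and 11.2 RPM. Both were picked after their values were seen.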
